A study of Homo sapiens with 8 samples.

How the data were processed

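RNA was measured by sequencing in NALM6, an established human B-cell precursor acute lymphoblastic leukemia line, carrying a doxycycline-inducible HMGN1 construct. HMGN1 is a protein that binds nucleosomes, and its gene lies on chromosome 21. The construct encoded either wild-type HMGN1 (WT) or a mutant with 2 serines exchanged that does not bind nucleosomes (SE). Per the labels' protocols, cells received doxycycline (DOX) at 100 ng/ml or vehicle for 6 hours, RNA was isolated from an equal number of cells per sample, every RNA sample received 1 µl of a 1000-fold dilution of the ERCC mix, and libraries were made with a poly(A) TruSeq kit. ERCC spike-ins are synthetic RNAs of known amount, added so that levels can be expressed per cell.

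The 8 libraries fall into 4 groups of 2: WT vehicle, WT DOX, SE vehicle and SE DOX. Groups come from the treatment and genotype labels, and the letters A and B from the labels' replicate description. Per the labels these are biological replicates, and how the cultures were kept apart is not given in the sources used here.

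The authors deposited 2 tables of FPKM (fragments per kilobase of transcript scaled to the mapped fragments), 1 unnormalized and 1 normalized, with the same 23713 rows, of which 92 are spike-ins. Per the submitters' processing notes, HISAT, Cufflinks 2.0.0 and the hg19 genome were used. The normalization method is not given in the sources used here. In the normalized table the spike-in sum was nearly equal in every library, between 7050 and 7166, while it ran from 5675 to 10042 in the unnormalized table, and no value was 0: values at 0 in the unnormalized table stand at 0.0718 to 0.135 in the normalized one, a floor whose origin is not given. The files hold no read counts, so the depth of each library is unknown and no counting interval can be given. No coordinates are printed, since the reference annotation at hand is of another genome build. FPKM values of genes with near-identical copies, of overlapping genes and of read-through transcripts are uncertain because reads can be divided between them. The kit is not known to mark strand, so a gene and its antisense partner cannot be told apart.

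Values were analysed as log2(spike-in-normalized FPKM + 0.1), leaving out spike-ins and genes with a mean under 1 over the 8 libraries, which left 11465 genes. Fold changes are on this scale, which understates the change of low genes. Of the genes tested, 302 have names of small RNAs (starting MIR, SNOR, SCARNA, RNU, RN7 or RNA5). Reads of overlapping poly(A) transcripts can fall on such rows. Such a row is therefore not shown to measure the small RNA itself. limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend) was fitted to the means of all 4 groups, which then share the estimate of the spread, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were DOX against vehicle within each construct, the difference of those effects (interaction) and WT against SE in vehicle. WT against SE in DOX was added after the data were seen. Global shifts were taken as the median log2 fold change over the genes tested, with an exact two-sided permutation test on library medians. With 2 libraries against 2 there are 6 splits, and the smallest p is 0.333, so this test cannot reach 0.05. For the difference of these medians between constructs it was run on the same-letter pair values, which takes letters as pairs. With 2 pairs against 2 the smallest p is also 0.333.

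Before the data were examined, 26 gene lists were written. Of these, 22 had at least 2 tested members and were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry, adjusted over the lists. The other 4 were not tested as lists: none of the mitochondrially encoded genes was among the rows given, no erythroid marker was tested (highest unnormalized FPKM 0.0648), and the T-cell and adherent cell lists had 1 tested member each (GATA3 and TAGLN). Genes named per comparison are HMGN1, the 10 largest rises and 10 largest falls past the threshold whose groups do not overlap, filled up to 10 by smallest p among genes with an absolute log2 fold change of at least 0.58, the 3 members of smallest p per list, and any tested HMGN or 21q22 gene. Small RNA, LOC and LINC names are skipped by that rule, and where small RNAs are named below they were chosen after their values were seen. A gene that the rule selects is not reported here.

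The fit was tested on simulated data with 200 changed genes in the WT DOX libraries. Over 11465 genes it recovered 0% of genes changed by 0.5 on the log2 scale, 34% of those raised by 1, 28% of those lowered by 1 and 86% of those raised by 2, with 5 false calls. The simulated noise was independent between genes and libraries. Deviations shared by same-letter libraries or by all genes of a library were not simulated, so these rates may not hold for the data. Alternatives were the unnormalized table, equal library medians, 1 spike-in factor per library, pseudocounts of 1 and 0.01, no filter or a mean of at least 5, small RNA names left out, a replicate block, no trend, fewer groups in the fit and each library left out. Several combinations were added after the data were seen.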

Results

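The data are poly(A) RNA levels in 8 NALM6 libraries, 2 each from cells with wild-type HMGN1 or the nucleosome-binding mutant, given vehicle or DOX for 6 hours. The series title names HMGN1 overexpression as a route to global amplification of transcription, and the spike-ins allow levels per cell to be compared. Depth is unknown because FPKM values carry no counts. The tested cells expressed the B-lineage list in full, with 30 of 30 members above the minimum, whereas 0 of 13 erythroid markers, 1 of 12 T-cell markers and 3 of 14 myeloid markers were.

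HMGN1, the gene to be induced, was not higher in the libraries labelled DOX. In the unnormalized table the WT libraries held 809.2 (A) and 796 (B) FPKM in vehicle and 792.9 (A) and 795.3 (B) in DOX. The SE libraries held 1427 (A) and 1066 (B) FPKM in vehicle and 1421 (A) and 1061 (B) in DOX. On the spike-in scale, WT HMGN1 was 932 ± 126 (SD, n = 2) FPKM in vehicle and 905 ± 96.1 (SD, n = 2) in DOX, and SE HMGN1 was 1177 ± 182 (SD, n = 2) and 985 ± 25.2 (SD, n = 2). The log2 fold change was -0.04 (95% interval -0.60 to 0.52) in WT and -0.25 (-0.81 to 0.32) in SE, with limma adjusted p of 1 and 0.537. The interval for WT ends at 1.44-fold. HMGN1 has processed pseudogenes and the row does not say whether construct transcripts are counted on it, so the value does not verify the treatment labels. Directions below are therefore those of libraries labelled DOX against libraries labelled vehicle. The other HMGN genes gave similar values in WT: HMGN2, HMGN3, HMGN4 and HMGN5 had log2 fold changes of -0.06, -0.04, -0.03 and -0.07.

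**Figure D1:**
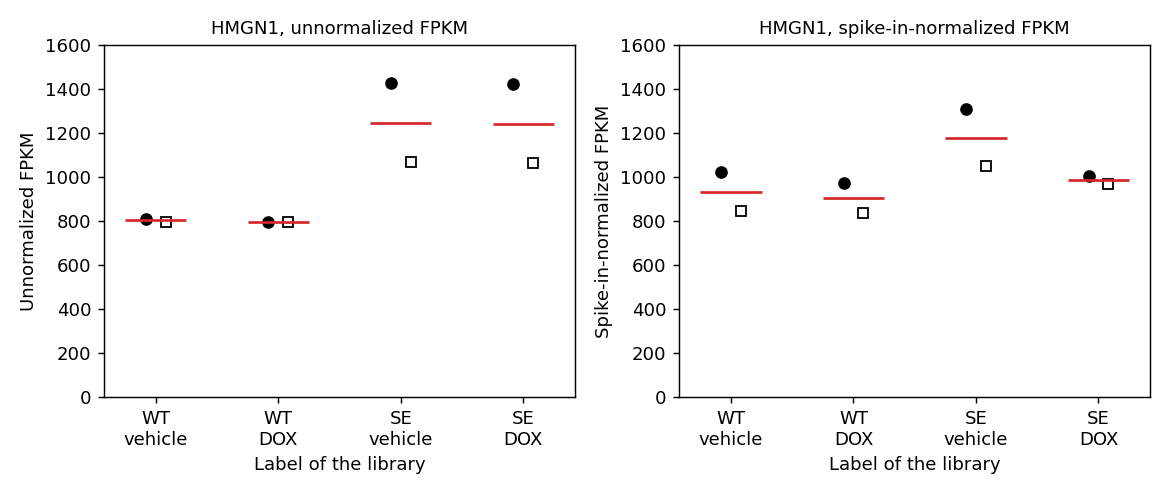
HMGN1 FPKM in each library, by its label, in the unnormalized table (left) and the spike-in-normalized table (right). Filled circles are letter A, open squares letter B and red lines group means. Unnormalized WT values lie between 792.9 and 809.2 in vehicle and DOX alike.

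The question of global amplification is whether the whole distribution of transcript levels rose per cell. In WT no rise was found: the median log2 fold change over 11465 genes was -0.03, with pair values of -0.02 (A) and -0.05 (B), and 75.0% of genes were below 0. In SE the median was -0.24, with pair values of -0.35 (A) and -0.13 (B), and 98.3% of genes were below 0. The exact two-sided permutation p on library medians was 0.667 in each construct. WT minus SE differed by 0.21 (exact permutation p = 0.333 on the same-letter pair values, the smallest possible). The WT median was 0.07 without WT vehicle letter A and 0.09 without WT DOX letter B. Leaving out 1 library also unbalances the letters, and WT library medians were higher in A (4.232 and 4.216) than in B (4.027 and 3.991). Those positive values therefore hold the letter difference too, and 2 pairs do not fix the sign. The size of the SE value depends on the SE DOX library of letter A. Without that library the median was -0.05 and the difference 0.02, again with unbalanced letters, while pair B alone had -0.13. Without the spike-in scale, in the unnormalized table, the medians were -0.0019 in WT and -0.000469 in SE. FPKM scaled to mapped fragments removes a change shared by all genes, so these values do not test global amplification.

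The spike-ins themselves carried this shift. Their share of the unnormalized values was 0.531% and 0.558% in the WT vehicle libraries and 0.538% and 0.569% in WT DOX. It was 0.826% and 0.719% in SE vehicle and 1.06% and 0.763% in SE DOX. Over 40 spike-ins with a mean of at least 1, the median log2 ratio of DOX to vehicle was 0.02 and 0.05 in the WT pairs and 0.34 and 0.12 in the SE pairs. Over the 20 most abundant spike-ins the median in the SE pair of letter A was 0.35, with an SD of 0.13 over species. The shift was alike at all levels of expression. A factor applied to a whole library moves all levels alike on the log2 scale. The class medians therefore do not tell a change of RNA per cell from a change of spike-in amount. In 5 classes of 2293 genes, WT medians ran from -0.02 in the lowest class to -0.04 in the highest, and SE medians from -0.23 to -0.24.

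**Figure D2:**
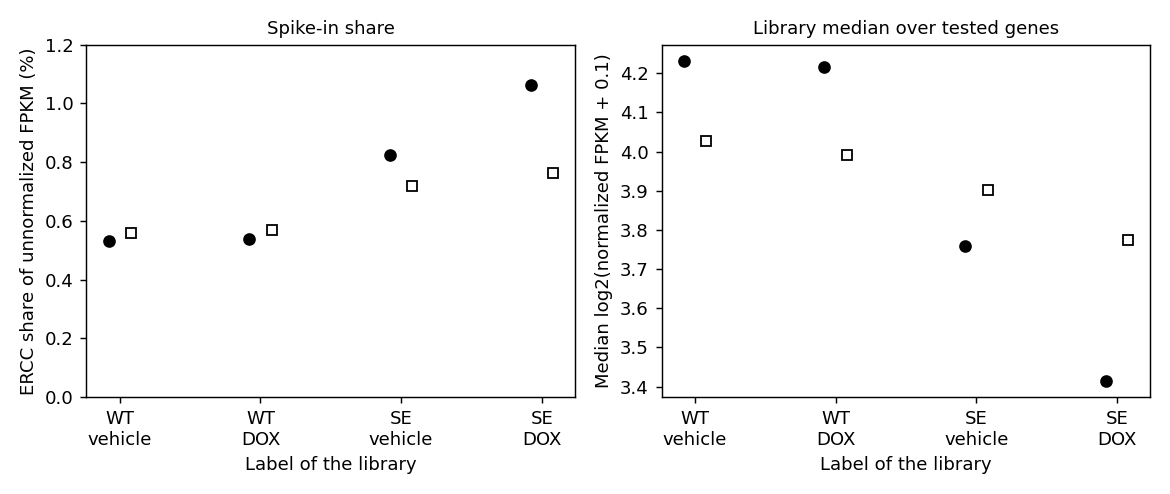
Share of unnormalized FPKM held by ERCC spike-ins (left, %) and median log2 spike-in-normalized level over tested genes (right, axis not from 0), per library. Filled circles are letter A and open squares letter B. SE DOX letter A has the highest spike-in share, 1.06%, and the lowest median, 3.41.

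In the WT libraries labelled DOX, in the fit without a replicate block, no gene passed the test apart from rows of small RNAs. limma called 8 genes, 3 higher and 5 lower at adjusted p under 0.05, and all 8 have small RNA names, while 37 genes had an unadjusted p under 0.05. With small RNA names left out, limma called 0 of 11163 genes and 14 had an unadjusted p under 0.05. The called rows were at 0.0191 unnormalized FPKM or less in both libraries of 1 group, where the normalized table holds 0.0987 to 0.121, so their folds rest on that floor. The row SNORD116-20, named for a small nucleolar RNA, was 7.72 higher on the log2 scale (SE 0.25, adjusted p = 5.93e-07). MIR3651, a row named for a microRNA, had a log2 fold change of -8.63 (SE 0.36, adjusted p = 3.56e-06). Other genes picked by the naming rule did not pass in this fit. IFITM1, an interferon-induced membrane protein, had a log2 fold change of -0.88 (SE 0.38, adjusted p = 1). The read-through row POC1B-GALNT4 had 0.95, the antisense row MED4-AS1 had 0.70 and TEX40 had -0.59, each with adjusted p = 1. H3F3A, the histone H3.3 gene with many pseudogenes, had a log2 fold change of 2.57 (SE 0.94, unadjusted p = 0.022) and did not pass either. The rule leaves it out because its groups overlap, at 2.42 (A) and 0.119 (B) normalized FPKM in vehicle and 8.67 (A) and 2.11 (B) in DOX. Each DOX value exceeded the vehicle value of its letter, but 0.119 lies at the floor of the normalized table. In SE it was 3.68 against 1.8 (A) and 4.75 against 1.86 (B). With a replicate block, equal medians and small RNA names left out, H3F3A and IFITM1 were called in WT, as given in the section on processing. That holds only if letters pair the samples. Leaving out single libraries gave 9 to 27 calls, the most without WT DOX letter B.

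Gene groups in WT lay close to the whole. Medians of the 22 lists ran from -0.06 to 0.02, no member of any list passed over all genes or adjusted over the list alone, and none passed camera (lowest adjusted p 0.386) or fry (lowest 0.957). Cytosolic ribosomal proteins had a median of -0.06 over 76 genes, with RPL21, RPS21 and RPS28 at -0.47, -0.12 and -0.12. The 30 B-lineage genes had a median of -0.02, with CD79B and CD72, both B-cell surface proteins, at -0.09 and -0.11. The 27 immediate early genes, among them IER3, DUSP2 and JUND at -0.19, -0.17 and -0.13, had a median of -0.05. RNA polymerase II machinery (41 genes) had a median of -0.04 and the 20 tested genes of the 21q22 segment -0.03. Precision was limited in this fit without a replicate block: the median half-width of a gene's 95% interval was 0.50 on the log2 scale. With a replicate block, equal medians and small RNA names left out it was 0.0987. That holds only if letters pair the samples, and equal medians take out any shift shared by all genes.

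The SE libraries labelled DOX, again in the fit without a replicate block, gave calls in small RNA rows. limma called 6 genes, 4 higher and 2 lower, all with small RNA names, among them MIR4312, MIR130B and SNORD116-20 (higher as in WT, at 7.20), and 50 genes had an unadjusted p under 0.05. SNORA36A, also called in both constructs, went opposite ways, at -5.35 in WT and 5.01 in SE. Each of the 6 rows was at 0 unnormalized FPKM in both libraries of 1 group, so these folds rest on the floor too. Without small RNA names 1 gene was called, INO80B-WBP1, a read-through row at -3.23 (SE 0.55, adjusted p = 0.0115; SE 0.96 and adjusted p = 0.537 with them kept), and with equal medians as well it was not called (-2.99, adjusted p = 1). CDRT15 (-0.73), FAM229A (-0.64), HIST1H2BC (0.72) and H3F3A (1.15) did not pass in this fit. With only the SE groups in the fit limma called 138 genes, 76 higher and 62 lower. Leaving out single libraries gave 8 to 25 calls, the most without SE DOX letter B.

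The lists followed the shift of all genes in SE, with medians from -0.28 to -0.22 against -0.24 overall. Camera with the preset correlation set cytosolic ribosomal proteins (median -0.23, adjusted p = 7.78e-05), nuclear-encoded respiratory chain genes (-0.23, adjusted p = 0.0489) and replication-dependent histones above other genes (adjusted p = 7.78e-05). With an estimated correlation each had adjusted p = 0.997. The histone list had a median of -0.28, which lies below that of all genes, so median and test differ in sign. No member of these lists passed over all genes or adjusted over the list alone.

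The test of the difference between constructs called 9 genes, 4 with a higher and 5 with a lower effect in WT, all with small RNA names, and 33 had an unadjusted p under 0.05. Without those names limma called 1, again INO80B-WBP1 (4.69, SE 0.78, adjusted p = 0.00689; adjusted p = 0.83 with them kept), and with equal medians as well it was not called (4.48, adjusted p = 1). RPL23AP64 and SPATA24 had 0.64 and 0.69 and did not pass. Leaving out single libraries gave 17 to 36 calls, the most without WT vehicle letter A. Medians of the lists ran from 0.17 to 0.24, beside 0.21 for all genes. Cytosolic ribosomal proteins (adjusted p = 0.000307) and respiratory chain genes (adjusted p = 0.0451) were below other genes in camera, and with an estimated correlation each had adjusted p = 0.985.

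**Figure D3:**
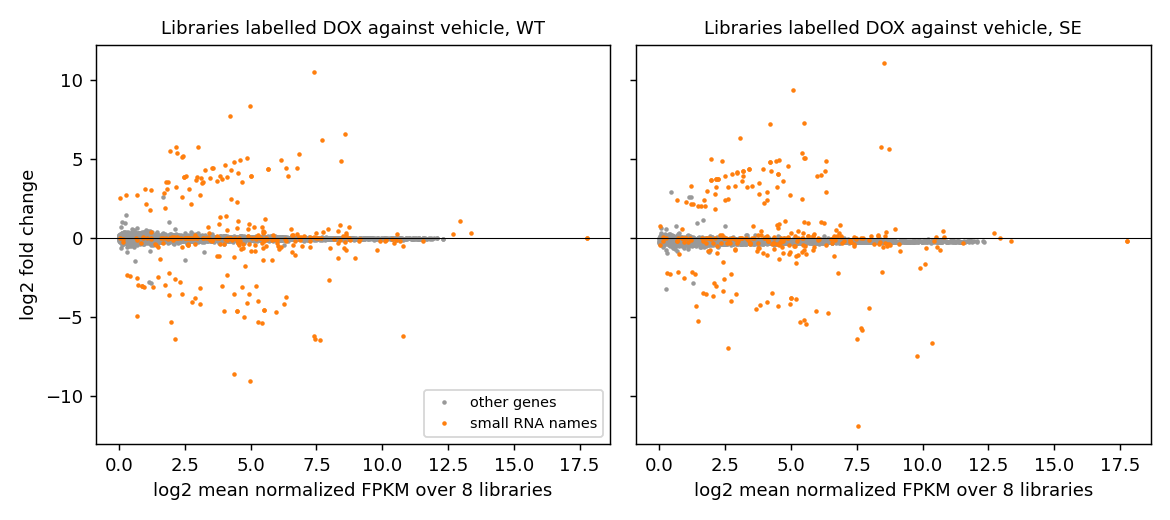
log2 fold change of libraries labelled DOX against vehicle, by log2 mean normalized FPKM, for WT (left) and SE (right). Each point is a tested gene and orange points have small RNA names. Orange points spread widely while grey points stay near the medians of -0.03 and -0.24.

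The WT and SE libraries differed in some genes before DOX. In vehicle limma called 21 genes, 7 higher and 14 lower in WT, of which 9 have other than small RNA names. WBP5, listed at 0 in every unnormalized WT library, was 13.5 ± 0.585 (SD, n = 2) FPKM in the SE vehicle libraries and had a log2 fold change of -5.90 (SE 0.28, adjusted p = 8.1e-06). The size of that fold rests on the floor of the normalized table, where WBP5 stands at 0.119 and 0.114 in WT vehicle, and a listed 0 does not show that the transcript is absent. SOHLH2 stands near that floor too, at 0.136 and 0.112. SOHLH2, a germ-cell transcription factor, had -4.17, PRKACB, a catalytic subunit of protein kinase A, -3.04, and GNG11, a G-protein subunit, -2.67. The zinc finger gene ZNF354B had -1.98. DAZ2 and DAZ4, near-identical copies between which reads can be divided, had -2.14 and -2.15. PRAF2 was the called gene higher in WT, at 9.59 ± 0.128 against 3.28 ± 0.568 (SD, n = 2) normalized FPKM, a log2 fold change of 1.53 (SE 0.18, adjusted p = 0.00664). With equal library medians 3 of these were not called, at log2 fold changes of -3.34 for PRKACB (SE 0.41, adjusted p = 0.0641; SE 0.48 before), -2.96 for GNG11 (SE 0.53, adjusted p = 0.264; SE 0.41 before) and 1.23 for PRAF2 (SE 0.18, adjusted p = 0.119). The first 2 folds are larger than before and the third smaller, and why the calls ended was not tested. Below the threshold came EFNB2 (0.95), TP53I3 (0.90), S100A4 (1.01), NAALADL2 (2.63) and SAMHD1 (1.22). Without small RNA names the count was 55, with 41 higher and 14 lower, and the added scaling to equal medians turned this to 1 higher and 9 lower. Leaving out single libraries gave 22 to 46 calls, the most without WT vehicle letter B.

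HMGN1 itself had a log2 fold change of -0.33 (95% interval -0.90 to 0.23, adjusted p = 0.349) in WT against SE in vehicle, and -0.62 (adjusted p = 0.617) in the unnormalized table. Most genes stood higher in WT than in SE on the spike-in scale, with a median of 0.32 and 93.3% of genes above 0. HMGN1 lay on the other side, while HMGN2, HMGN3, HMGN4 and HMGN5 had 0.23, 0.31, 0.32 and 0.31. Unnormalized HMGN1 was 792.9 to 809.2 FPKM over WT vehicle and DOX libraries and 1061 to 1427 over SE ones, without overlap. The HMGN1 p-values are adjusted over all genes tested, so they do not show equal HMGN1 in the constructs. The cause of the higher SE values was not tested. Library medians averaged 4.13 ± 0.145 in WT and 3.83 ± 0.101 in SE vehicle (SD, n = 2, exact permutation p = 0.333). Against that shift, the 20 tested p53 targets had a median of 0.03, and camera set them below other genes (adjusted p = 1.04e-06, and adjusted p = 0.908 with an estimated correlation). Among them TP53I3 had 0.90, PHLDA3 -0.81 and BBC3 -0.37, and 1 member, higher, passed when adjusted over the list alone. Immediate early genes (median 0.18, adjusted p = 0.00764) and cholesterol synthesis genes (median 0.15, adjusted p = 0.0375) were also below other genes, and each had adjusted p = 0.908 with an estimated correlation. None of the B-lineage genes passed, CD38, CD79A and CD22 having 0.78, 0.77 and 1.02.

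In the libraries labelled DOX, a comparison added after the data were seen, WT against SE gave 12 calls, 4 higher and 8 lower. The count was 520 without small RNA names, 507 higher and 13 lower, and with equal medians as well 9, 1 higher and 8 lower. PRAF2 (1.76), S100A4 (1.31), EFNB2 (1.18) and TP53I3 (1.07) were higher in WT (SE 0.18, 0.18, 0.16 and 0.15), and WBP5 (-5.68) and SOHLH2 (-3.93) were among those lower. With equal medians none of the first 4 was called: PRAF2 had 1.25 (SE 0.18, adjusted p = 0.131), S100A4 0.801 (SE 0.098, adjusted p = 0.0915), EFNB2 0.667 (SE 0.086, adjusted p = 0.103) and TP53I3 0.558 (SE 0.13, adjusted p = 0.598). WBP5 and SOHLH2 stayed called. HMGN1 had -0.13 (95% interval -0.69 to 0.44, adjusted p = 0.647), and -0.63 (adjusted p = 0.649) in the unnormalized table.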

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

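The test of on/off values was set before its result was seen, and the other tests here were chosen after the results were seen. Groups of 2 are too small for a check of outlying libraries.

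A test of the difference between constructs picked out 9 small RNA rows. The effect of the DOX label in WT minus that in SE was 11.89 for MIR4312, 6.92 for MIR641, 6.64 for SNORA68, 5.90 for MIR1307, -6.40 for MIR3944, -7.35 for SNORD116-4, -8.67 for MIR3651, -9.35 for MIR130B and -10.36 for SNORA36A on the log2 scale. Small RNA rows changed by over 2-fold between same-letter libraries in 31.8% to 38.7% of cases, other genes in 0.0627% to 0.152%. If the on/off values did not follow treatment, rows on in 2 libraries and at 0 in 2 would be divided by treatment no more often than by letter or crosswise. In WT 34 such rows gave 12 by treatment, 10 by letter and 12 crosswise, and in SE 34 gave 11, 13 and 10. The ratio of treatment splits to the mean of the other splits was 1.02, so on/off noise of short rows may account for these calls. A biological response of the transcripts counted on single rows stays open, and these need not be the small RNAs.

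HMGN1 was not higher in libraries labelled DOX. An exchange of letter and treatment marks within a construct that hides a rise of at least 2-fold predicts letters that differ by 1 on the log2 scale, and unnormalized HMGN1 differed between letters by 0.00966 in WT and 0.421 in SE, which argues against it, by a bound that was changed after the values were seen and then set back to the first one written. A hidden rise below 2-fold stays open, as A lay above B in both SE pairs. In WT HMGN1 lay higher in A on the spike-in scale by 0.276 (vehicle) and 0.217 (DOX). WT library medians over all genes were also higher in A, at 4.232 against 4.027 in vehicle and 4.216 against 3.991 in DOX. Unnormalized WT HMGN1 differed by 0.0238 and -0.00443, so the WT spike-in values are no sign of a hidden rise by themselves. Whether the construct's transcript is counted on this row cannot be told apart from absent induction: the largest same-letter difference in unnormalized HMGN1 was 0.0294, and no row in the tables carries the construct alone. No same-letter pair showed a rise on this row on the spike-in scale, at -0.0699 (A) and -0.0114 (B) in WT and -0.38 and -0.116 in SE. By the fit without a block, an induction inside its interval stays open. With a replicate block, equal medians and small RNA names left out, the WT interval ended at 1.071-fold, which holds only if letters pair the samples.

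WT libraries lay above SE libraries on the spike-in scale, in vehicle and in DOX. MIR1244-2 and MIR1244-3 together took 39.8% to 47.3% of the FPKM in WT and 38.2% to 40.9% in SE. By this measure the share is not higher in SE, as the explanation by a few rows needs. FPKM divides by transcript length, so a share of FPKM is not a share of fragments. The shift computed by treating it as one, -0.107 with a combined SD of 0.135, therefore does not measure the effect of these rows. It was computed with a bound chosen once the values were known and is not used to exclude the explanation. A share of fragments taken by a few rows lowers the FPKM of genes and spike-ins of a library alike, so 1 spike-in factor per library removes it. With that factor the WT minus SE difference of library medians in vehicle was 0.225, with a combined SD of 0.186. The spread is as large as the distance to the bound set for this explanation, so whether a difference remains is not settled. In the unnormalized table, whose scale removes a difference shared by all genes, it was -0.00657, so the difference shows only with the spike-in scaling. More spike-in per cell in the SE samples and less RNA per SE cell cannot be told apart, since nothing in the tables measures either by itself. A difference between the constructs stays open.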

How the results depend on the processing

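Combinations of settings and all settings without small RNA names joined to another choice were added after the data were seen. HMGN1 was not called under any alternative run, in any comparison, with adjustment over all genes tested, but its fold moved in WT against SE. In vehicle it went from -0.33 to -0.62 unnormalized and -0.63 with equal medians, and in DOX from -0.13 to -0.63 and -0.64. Every unnormalized SE value of HMGN1, at 1061 FPKM or more, lay above every WT value, at 809.2 or less.

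Counts of genes called moved as follows. For DOX in WT (8), they were 5 in the unnormalized table, 5 with equal medians, 5 with a mean of at least 5 and 0 without small RNA names. For SE (6), 1 without small RNA names and 138 with only the groups compared in the fit. For the interaction (9), 5 in the unnormalized table and 1 without small RNA names. At baseline (21), 11 with a mean of at least 5, 55 without small RNA names and 32 with only the groups compared. Without small RNA names and with equal medians, the counts were 0, 0, 0 and 10. Leaving out single libraries gave 9 to 27, 8 to 25, 17 to 36 and 22 to 46 calls.

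Same-letter libraries deviated together with r = 0.0863 in WT and 0.116 in SE over the genes tested, and with rank correlations of 0.759 and 0.724. As r misses 0.1 in WT and the labels name no shared day or batch, the letters were not taken to pair the samples. Without small RNA names, a choice made after seeing this, r was 0.767 and 0.739. The low r thus came from the small RNA rows, and over the other genes libraries of a letter deviated together. With equal medians as well, same-letter libraries of a construct lay closer together than different letters within a group. The median absolute log2 difference was 0.0379 to 0.0523 against 0.107 to 0.127. The main fits count these differences between letters as spread, so they can miss effects of DOX that a paired test would call. What the letters stand for is not given, so the blocked counts below hold only if letters pair the samples. Fits with the block had been run before this was judged. The replicate block gave 181 calls (88 higher, 93 lower) in WT, 1663 (94 and 1569) in SE and 227 in the interaction. Without small RNA names the block gave 17, 320, 31 and, at baseline, 153. With equal medians as well it gave 2 (H3F3A at 2.6 and IFITM1 at -0.847, adjusted p = 0.0105 for each), 0 and 0, and HMGN1 intervals of 0.9199- to 1.071-fold in WT and 0.9236- to 1.075-fold in SE, which hold only if letters pair the samples, where the simulated WT comparison over 11163 genes recovered 82% of genes changed by 0.5.

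The medians depend on the spike-in scale. In WT the median was -0.0019 unnormalized (a scale that removes a change shared by all genes), -0.0063 with equal medians (which sets it near 0 by construction) and -0.0030 with 1 spike-in factor. In SE it was -0.000469 and -0.0037, and the difference -0.0014 and -0.0025, for the first 2 of these. With 1 spike-in factor the SE median was -0.288 and the difference 0.285, beside -0.24 and 0.208 in the main setting. Leaving out single libraries gave -0.15 to 0.089 in WT, -0.43 to -0.049 in SE and 0.016 to 0.40 for the difference. Each such omission also unbalances the letters. The spike-in log2 ratio of DOX to vehicle was 0.04 in WT (-0.080 to 0.17 with libraries left out) and 0.23 in SE (0.050 to 0.42). A lone remaining library was taken to vary like the other groups.

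Lists past camera moved from 0 to 1 in WT unnormalized and to 2 without small RNA names, from 3 to 0 in SE with the block, equal medians, the unnormalized table or an estimated correlation, and from 2 in the interaction to 0, 0, 1 and 0. At baseline 3 became 9 with equal medians, 9 unnormalized and 0 with an estimated correlation. SE, the interaction and baseline had 5, 4 and 5 without small RNA names, and with the block and equal medians as well the 4 comparisons had 2, 1, 3 and 11. With an estimated correlation each of these was 0. The cause of these changes was not tested. Depth is unknown, so its effect could not be examined.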

Other observations

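All tests in this part were chosen after the data were seen, and no explanation was tested. They set letter A against letter B within a construct, with treatment as a term, small RNA names left out and equal library medians. The 2 libraries of a letter are taken as repeats, which the labels do not state beyond a shared letter, so the p-values measure only the spread between those libraries.

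Replicates of a construct differed far more than treatments did. The median absolute log2 difference was 0.0379 to 0.0523 between vehicle and DOX libraries of the same construct and letter, and 0.107 to 0.127 between letters within a group. Between WT and SE libraries of the same letter it was 0.168 to 0.177 for A but 0.0739 to 0.086 for B, so by this median the B libraries of the 2 constructs lay closer to each other than to the A libraries of their own construct. By genes over 2-fold this held for WT (51 to 69 between the B libraries, 115 to 132 between WT letters) but not for SE (44 to 55 between SE letters). limma gave 4989 of 11163 genes different between letters in WT and 4383 in SE. In WT letter B, MSH6, a DNA mismatch repair gene, was 7.70 (vehicle) and 7.90 (DOX) unnormalized FPKM, against 30.9 to 37.5 in the other 6 libraries, and the log2 difference A minus B was 2.21 (SE 0.03, adjusted p = 6.16e-11). In WT letter A, DDIT4L, a stress-induced gene, was 5.55 and 5.64 against 33.3 and 34.2 in letter B. NPY, a neuropeptide, was 11.5 and 12.3 against 50.5 and 47.0, and TNFAIP3, an inhibitor of NF-κB signalling, was 8.58 and 8.75 against 22.9 and 22.4.

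Members of some gene lists lay to 1 side between letters, though no list passed camera with an estimated correlation. In WT, 68 of 76 cytosolic ribosomal protein genes were higher in A (median 0.31, camera adjusted p = 5.95e-15, and adjusted p = 0.476 with an estimated correlation), while 25 of 30 G2/M genes (median -0.19) and 11 of 15 heat shock genes (median -0.21) were lower, among them HSPH1 at -0.42. In SE, 27 of 30 G1/S genes (median -0.20) and 14 of 15 heat shock genes (median -0.24) were lower in A, and 10 of 12 replication-dependent histone genes were higher (median 0.82). With an estimated correlation these lists had camera adjusted p from 0.346 to 0.476. Fry, which does not compare a list with other genes, gave adjusted p of 0.0386, 0.0139 and 0.0214 for the 3 lists in WT, in that order, and 0.00792, 0.0204 and 0.0537 for those in SE. Across 11163 genes the differences between letters had a correlation of 0.08 between the constructs, and genes are not independent replicates. Of genes called in both, 1087 differed in the same direction and 1116 in opposite directions.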
